A study of Mus musculus with 4 samples.

How the data were processed

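Messenger RNA was measured in the right testis of 4 sexually mature male mice of the outbred KM (Kunming) strain. Per the labels' protocols, the left testis of the hemicastrated mice had been removed before puberty, the control mice had a sham operation at the same time, and the right testis was taken at maturity and frozen. The series' design text gives 2 mice per group, and the sample labels give 2 hemicastrated and 2 control libraries, whereas the protocol text speaks of 3 mice per group. The 4 libraries are treated here as 4 separate mice, since the extraction protocol states that RNA of 4 individuals was used. The labels name the molecule as genomic DNA while the protocol describes RNA, and the values were read as RNA. DNA methylation, which the series title also names, was not analysed here.

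Per the labels' protocols, poly(A) RNA was selected from total RNA, fragmented and reverse transcribed with random primers into double-stranded cDNA for Illumina sequencing. The protocol describes no step that marks the strand, so reads of a gene and of an antisense or overlapping partner could not be told apart. The submitters' processing notes name TopHat2 2.0.11, Cufflinks 2.2.1 and the genome build GRCm38, without stating their roles, and the gene annotation is not given in the sources used here. The deposited values are FPKM (fragments scaled to the length of the transcript and to the number of mapped fragments), 1 value per gene and library, per the file headers and as made by the authors. The table holds 22073 gene identifiers, of which 3486 are at 0 in all 4 libraries.

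FPKM values carry no read counts. The smallest values above 0 are those of likelihood estimates rather than multiples of 1 read, so neither the depth of the libraries nor whole reads could be recovered, and no counting interval or detection limit is given. An exact 0 can be a failed estimate: the ribosomal protein genes Rpl13 and Rpl17 are listed at 0 in all 4 libraries and Rps12 in 3 of them. Genes at 0 are therefore described as listed at 0, with the value of each library and with no fold against a group at 0. The summed FPKM was 346632 and 344316 in the control libraries and 343105 and 353135 in the hemicastrated libraries.

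Symbols and positions were taken from GENCODE release M21 (GRCm38), which named 21806 of the 22073 identifiers and left 267 without a symbol. This annotation may differ from the one the authors used. Groups were taken from the labels alone. Libraries are called control 1, control 2, hemicastrated 1 and hemicastrated 2 after their titles.

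Genes with a mean of at least 1 FPKM over the 4 libraries were tested (11343 genes). FPKM plus a pseudocount of 1 was transformed to log2 and the groups were compared with limma 3.58.1 in R 4.3.3, with a trend of the variance on mean expression and no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Fold changes are hemicastrated minus control on the log2(FPKM + 1) scale, which understates the change of genes with low values. An exact permutation test of 1 gene, 2 libraries against 2, cannot give a two-sided p under 0.33, so calls rest on the spread that limma shares between genes. As a description without a p-value, genes were also counted whose group means were at least 2-fold apart with no overlap between the libraries of the groups, in the real split and in the other 2 ways to split the 4 libraries.

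Gene lists (27) for germ cell stages, somatic testis cells, other tissues that a testis sample could hold, and pathways that fit the operation were written before the data were examined. The 24 lists with at least 5 tested members were compared with all other tested genes by camera in limma, two-sided, with a preset inter-gene correlation of 0.01. The same test was run with the correlation estimated from the libraries, and fry, a rotation test of each list by itself, was run beside it. For each list the calls were also counted with p-values adjusted over the list alone. The rule for named genes was set at the same time. It takes, per direction, the 10 called genes with the largest absolute log2 fold change and no overlap between the libraries of the groups, per list up to 4 tested members (called ones first, then those with the smallest p), and a fixed set of protamines, transition proteins, hormone receptors, inhibins, steroidogenic enzymes and DNA methylation enzymes. Some genes that this rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

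The gene and list tests were first run on simulated data for the same comparison, with the means of the 11343 genes. Gene variances were drawn from the distribution that limma fitted to the real libraries, and 100 genes were changed 2-fold and 100 changed 4-fold in each of 20 runs. The test recovered 74.6% of the genes changed 2-fold and 98.9% of those changed 4-fold, and 4.67% of all calls were of unchanged genes. The simulated values followed the normal model that limma assumes, with no floor at 0, so these shares are not error rates of the real data. Of 20 simulated lists of 20 genes shifted by 0.2 on the log2 scale, 20 had an unadjusted p under 0.05 in camera with the preset correlation, and 1 of 20 unshifted lists did. The simulated genes varied independently of each other. In the real lists the estimated correlation ran from -0.0708 (gonadotropin, androgen and activin) to 0.502 (extracellular matrix). The simulation therefore does not show how the preset correlation performs on lists of correlated genes.

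Alternatives set before the data were examined were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, quantile normalization, median-of-ratios scaling, rescaling to TPM, limma without the trend, limma with robust hyperparameters, a block on the replicate number, leaving out each library in turn, a threshold of 0.1, and, for the lists, the estimated correlation and fry. A fit without genes whose symbols start with Defb, Wfdc or Spink, and a correction of fold changes for transcript length and GC content, were added after seeing the data. To find near-identical copies, the transcripts of called genes were compared with all GENCODE transcripts with BLAST 2.17.0, counting another gene's transcript with an alignment of at least 200 bases at 95% identity or more. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.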

Results

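Gene expression was measured by poly(A) RNA sequencing of the right testis of 2 mice whose left testis had been removed before puberty (hemicastrated) and of 2 sham-operated control mice, all of the outbred KM strain and all sampled after sexual maturity. The comparison asks which genes the remaining testis expresses at another level in the adult after the loss of its partner. Values are deposited FPKM per gene and library. Read depth is unknown, so precision is judged from the spread between the 2 libraries of a group. Of 22073 genes, 11343 had a mean of at least 1 FPKM and were tested. The protamine gene Prm1, expressed in late spermatids, had the highest value in each of the 4 libraries, at 5802 and 5995 FPKM in the controls and at 5732 and 6458 FPKM in the hemicastrated mice. The first principal component of the tested genes carried 66.7% of the variance and separated the groups. Across genes, which are not independent replicates, the Pearson correlation of log2 values was 0.9896 between the controls, 0.9871 between the hemicastrated libraries and 0.9693 to 0.9733 between libraries of different groups.

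Most of the called genes were lower after hemicastration, and the leading ones were high in both controls and near 0 in both hemicastrated libraries. In limma with Benjamini-Hochberg adjustment, 135 genes fell and 12 rose at an adjusted p under 0.05. The gene with the largest fall was Crisp1 (ENSMUSG00000025431, chromosome 17, 40293758 to 40319207, GRCm38), which encodes a secretory protein that coats sperm in the epididymis. Its FPKM was 545 and 786 in the controls and 0.0453 and 0.0391 in the hemicastrated mice, a log2 fold change of -9.30 (SE 0.17, adjusted p = 8.45e-06, limma). Cd52 (ENSMUSG00000000682, chromosome 4, 134082448 to 134095082), which encodes a surface glycoprotein of lymphocytes and of epididymal epithelium and sperm, fell from 360.8 ± 55.0 to 1.75 ± 0.51 FPKM (SD, n = 2 each; log2 fold change -7.04, limma adjusted p = 1.23e-05).

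Protease inhibitors and antimicrobial peptides made up most of the other leading genes. The Kazal-type inhibitor Spink8 stood at 206 and 299 FPKM in the controls against 3.19 and 4.45 (log2 fold change -5.70, SE 0.20). The beta-defensin Defb28 was at 184 and 301 FPKM in the controls, was listed at 0 in hemicastrated 1 and was at 0.522 in hemicastrated 2. Defb2, at 46.7 and 56.5 FPKM in the controls, was listed at 0 in both hemicastrated libraries. Wfdc15b, of the whey acidic protein domain family, was at 111 and 144 FPKM in the controls, listed at 0 in hemicastrated 1 and at 0.890 in hemicastrated 2. The serpin Serpina16 was at 64.9 and 68.6 FPKM in the controls, listed at 0 in hemicastrated 1 and at 0.0441 in hemicastrated 2. Serpina1f, of the same family, was at 46.9 and 69.1 FPKM against 0.163 and 0.359. The carboxylesterase Ces5a was at 93.9 and 108.7 FPKM against 0.612 and 1.44. Cuzd1, which encodes a protein with CUB and zona pellucida-like domains, was at 66.3 and 79.6 FPKM against 0.466 and 0.362. These 10 genes were past the threshold in all alternatives in which they were tested.

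**Figure D1:**
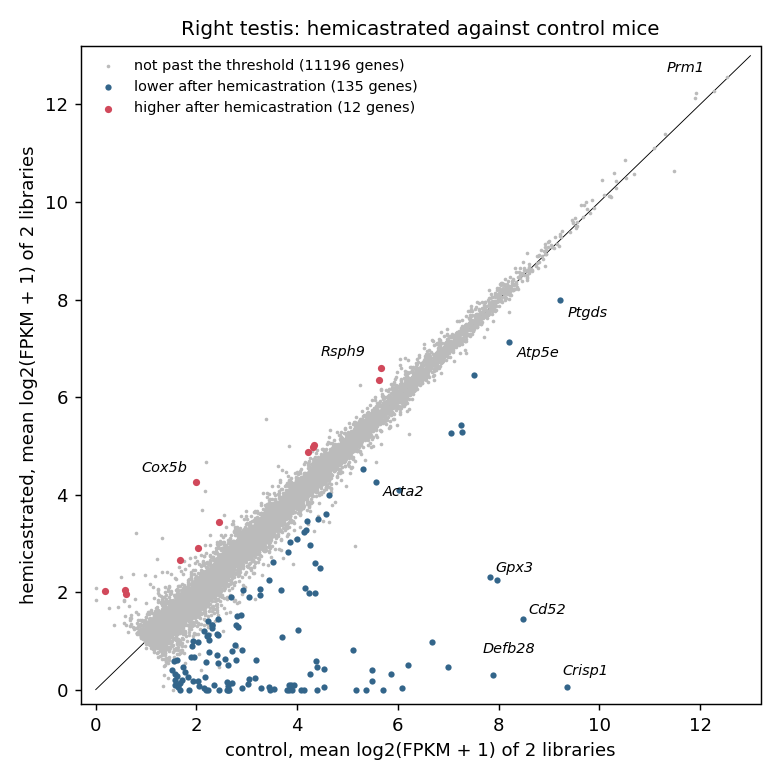
Mean log2(FPKM + 1) of the 2 control libraries (x axis) against that of the 2 hemicastrated libraries (y axis) for the 11343 tested genes, with the line of equal values. The 135 lower genes (blue) spread from just under the line, where Ptgds and Atp5e lie, to the bottom right, where Crisp1, Defb28 and Cd52 lie, while the 12 higher genes (red) lie close above the line.

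Of the 135 lower genes, 64 had both hemicastrated values under 10% of the control mean, 77 were under 1 FPKM in both hemicastrated libraries, 18 were listed at 0 in both, and 58 were at 1 FPKM or more in at least 1 of them. Their libraries did not overlap between the groups in 135 of 135 genes, which the call itself favours, since it needs a difference large against the spread. Together they took 1.32% and 1.58% of the summed FPKM in the controls and 0.254% and 0.233% in the hemicastrated mice. Without control 2 the count of lower genes was 78, and with genes of a mean of at least 5 FPKM alone, fewer being tested, it was 63.

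Among markers of other tissues, 2 epididymal genes fell, and no erythroid, endothelial or macrophage gene passed the test over all genes. Of 13 epididymis genes fixed as a list, 3 reached the filter, and 2 of them fell, also when adjusted over the list alone: Crisp1 and Adam7, a sperm surface protein made in the epididymis, at 18.6 and 21.4 FPKM in the controls and listed at 0 in both hemicastrated libraries. Rnase10, a secreted protein of the proximal epididymis, was at 2.02 and 1.28 FPKM in the controls against 1.59 and 1.70 (limma adjusted p = 0.995). Too few members were tested for the list test. None of the 3 tested erythroid genes was past the threshold (Hbb-bs 21.8 and 20.9 against 20.3 and 11.3 FPKM, median log2 fold change of the list -0.21). The log2 fold change of Hbb-bs was -0.87 without hemicastrated 1 and -0.07 without hemicastrated 2. In the endothelium list, 0 of 5 tested genes were called (median -0.02, camera adjusted p = 0.993, in which the test pointed up), with Egfl7 at 6.07 and 3.72 against 5.49 and 5.07 FPKM. In the macrophage list, 0 of 8 were called over all genes and 1 fell when adjusted over the list alone (median -0.04, camera adjusted p = 0.577). Of the 8, 4 had a positive and 4 a negative log2 fold change. Lyz2 was at 28.5 and 29.0 against 21.1 and 20.8 FPKM, Csf1r at 2.93 and 1.98 against 1.94 and 1.79, and C1qa at 6.25 and 5.72 against 6.28 and 4.66. Aif1, far above these 3 in each library, was at 203 and 210 against 219 and 213 FPKM. The median of the macrophage list was -0.26 without hemicastrated 1 and 0.07 without hemicastrated 2, and that of the endothelium list was -0.15 without control 2 and 0.11 without control 1.

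Smooth muscle genes were lower after hemicastration. Of 10 tested genes of the list for peritubular myoid cells (the contractile cells around the seminiferous tubules) and smooth muscle, 5 fell over all genes tested and 6 when adjusted over the list alone, and 10 had a negative log2 fold change, with a median of -1.02. Calponin Cnn1 fell from 5.80 ± 0.63 to 0.898 ± 0.094 FPKM (SD, n = 2 each; log2 fold change -1.84, limma adjusted p = 0.00192). Transgelin Tagln fell from 19.7 ± 4.0 to 5.06 ± 0.43 FPKM (log2 fold change -1.76, limma adjusted p = 0.00393), and an antisense gene shares its sequence. The tropomyosin Tpm2 was at 8.85 and 8.28 FPKM in the controls against 2.66 and 3.04 (log2 fold change -1.31), and the smooth muscle actin Acta2 at 53.0 and 40.2 against 19.4 and 17.1 (log2 fold change -1.29). The fifth gene, Des (desmin), named after its values were seen, had a log2 fold change of -1.22 and also has an antisense partner. The list had a camera adjusted p of 6.22e-10 with the preset correlation and an adjusted p = 0.754 with an estimated correlation. Acta2 missed the threshold without control 1 (adjusted p = 0.0675) and with no filter on low values (adjusted p = 0.0808), as did Tpm2 without control 1 (adjusted p = 0.0832) or control 2 (adjusted p = 0.0745). With no filter the median of the list was -0.65.

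Like the smooth muscle list, Crisp1 and Adam7, the extracellular matrix list was lower after hemicastration, though a single comparison cannot show a shared source. None of its 12 tested members was called over all genes and 3 fell when adjusted over the list alone, 11 of 12 had a negative log2 fold change, and the median was -0.48 (camera adjusted p = 0.00353; adjusted p = 0.754 with an estimated correlation). The proteoglycan genes Bgn and Dcn had log2 fold changes of -0.94 (SE 0.18) and -0.90 (SE 0.24). The collagen gene Col3a1 was at 11.4 and 5.50 FPKM in the controls and 3.63 and 1.87 in the hemicastrated mice (log2 fold change -1.30, and -0.83 without control 1), and Col1a1 at 3.33 and 1.16 against 0.710 and 0.623 (-0.88, and -0.38 without control 1). The list's median was -0.21 without control 1 (adjusted p = 0.0871), -0.75 without control 2, -0.31 under quantile normalization and -0.81 with a pseudocount of 0.1, and without hemicastrated 1 Dcn was called (log2 fold change -1.29, adjusted p = 0.00395).

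The 12 genes that rose did so by smaller steps, with log2 fold changes from 0.66 to 2.26. Cox5b (ENSMUSG00000061518, chromosome 1, 36691449 to 36693681), a nuclear-encoded subunit of cytochrome c oxidase, was at 3.12 and 2.88 FPKM in the controls and 25.5 and 12.8 in the hemicastrated mice (log2 fold change 2.26, SE 0.29, limma adjusted p = 0.0201). Rsph9, a radial spoke head protein of the axoneme, rose from 49.9 ± 0.2 to 96.1 ± 15.6 FPKM (SD, n = 2 each; log2 fold change 0.92, limma adjusted p = 0.0231). The centromere protein gene Itgb3bp rose from 19.2 ± 1.7 to 31.3 ± 0.3 FPKM (log2 fold change 0.68, limma adjusted p = 0.0405). The log2 fold change was 1.84 for Gm3543, 1.46 for A330070K13Rik, 0.99 for 1300017J02Rik, 0.99 for Ccdc122, 0.87 for Wdr95 and 0.74 for 4930415O20Rik. Lrrc43 and 1700125H20Rik, named after their values were seen, had log2 fold changes of 0.67 and 0.66. Near-identical copies make the values of Cox5b (copy Gm11273), Gm3543 (copy Gm10377) and Itgb3bp (copy Gm3507) uncertain.

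The count of higher genes in limma was 0 without control 2, where 1000 genes had an unadjusted p under 0.05 in either direction, 4 without control 1, 24 without hemicastrated 1, 26 without hemicastrated 2, 3 with no filter and 7 with a mean of at least 5 FPKM. Each of the 10 higher genes that the naming rule takes missed the threshold without either control library, with Cox5b at an adjusted p of 0.175 without control 1 and 0.209 without control 2. Cox5b also missed it with no filter (adjusted p = 0.123) and with robust hyperparameters (adjusted p = 0.0701), and Rsph9 with no filter (adjusted p = 0.108) and without the trend (adjusted p = 0.0614).

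**Figure D2:**
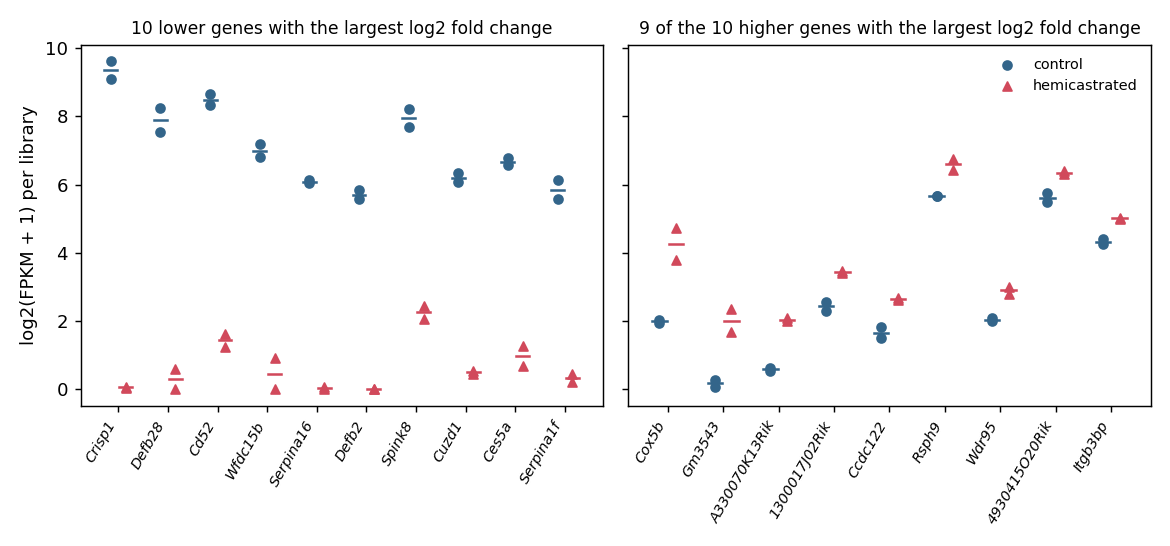
The log2(FPKM + 1) of each library (points) and the group mean (short lines) for the 10 lower (left) and 9 of the 10 higher genes (right) with the largest log2 fold change among called genes, control in blue circles and hemicastrated in red triangles. Only genes whose libraries do not overlap between the groups were taken, so the 2 control libraries of each gene lie apart from the 2 hemicastrated ones. Values run from Crisp1 at 545 and 786 FPKM against 0.0453 and 0.0391 to Itgb3bp at 18.0 and 20.4 against 31.1 and 31.5 FPKM.

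Germ cell genes of the fixed lists were not called singly. The round spermatid list was higher as a list: 22 of its 23 tested genes had a positive log2 fold change, with a median of 0.12, 0 were called over all genes and 0 when adjusted over the list alone (camera adjusted p = 7.62e-06; adjusted p = 0.754 with an estimated correlation). The log2 fold change was 0.45 (SE 0.09) for the lysozyme-like Lyzl1, 0.32 for Spaca1 and 0.27 for Acrv1, both acrosomal proteins, and 0.19 for Actl7b. The early meiotic prophase list had 16 of 22 tested genes with a positive log2 fold change and a median of 0.14, with 0 calls by either adjustment (camera adjusted p = 0.0104; adjusted p = 0.754 with an estimated correlation). Of its synaptonemal complex genes, Syce3 was at 109.5 and 113 FPKM in the controls against 152 and 138 (log2 fold change 0.38), Sycp3 at 57.6 and 63.4 against 90.7 and 73.1 (0.42) and Tex12 at 9.01 and 7.70 against 10.9 and 11.8 (0.41), and the meiotic axis gene Hormad1 had a log2 fold change of 0.48. Without hemicastrated 1 the median of this list was 0.04 and its adjusted p 0.3, and without hemicastrated 2 the median was 0.28. The adjusted p was 0.0837 without control 1 and 0.0519 under quantile normalization. The median was 0.21 with a mean of at least 5 FPKM and 0.08 with the length and GC correction. The genes that fell took 1.32% and 1.58% of the summed FPKM in the controls and 0.254% and 0.233% in the hemicastrated libraries.

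With all 4 libraries, the other germ cell lists were not past the threshold in either test. They had 0 calls over all genes and 0 over each list alone. The median log2 fold change was 0.002 for 17 pachytene spermatocyte genes (camera adjusted p = 0.396), with 0.17 for the chaperone Clgn and -0.21 for the helicase Hfm1. For 12 genes of differentiating spermatogonia the median was -0.06 (camera adjusted p = 0.577). Ccnd2 in this list was at 1.33 and 2.10 FPKM in the controls against 0.479 and 0.663, and Esx1 at 14.7 and 14.4 against 7.25 and 15.3. The log2 fold change of Esx1 was -0.92 without hemicastrated 2 and 0.06 without hemicastrated 1. Only 4 genes of undifferentiated spermatogonia were tested, too few for the list test, with Gfra1 at 1.55 and 1.35 FPKM against 0.945 and 1.26 and Id4 at 9.80 and 9.84 against 9.21 and 8.96. In the elongating spermatid list of 25 genes the median was -0.01, the mean 0.02 and the test pointed up (camera adjusted p = 0.577). Prm1 had a log2 fold change of 0.05, Prm2 of 0.24, and the transition protein genes Tnp1 and Tnp2 of 0.33 and 0.001, and none of these 4 passed the threshold over all genes (limma adjusted p of 0.413 to 0.998). Under quantile normalization the log2 fold changes of Prm2, Tnp1 and Tnp2 moved to 0, 0.16 and -0.16, and without hemicastrated 1 that of Prm2 was 0.11 and without control 1 that of Tnp1 0.16. In the axoneme and flagellum list the median of 22 genes was 0.05 (camera adjusted p = 0.133), with Ccdc39 at 19.7 and 23.2 FPKM in the controls against 35.6 and 24.4. The median of this list was 0.08 without hemicastrated 1 and 0.02 without control 2.

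Sertoli cells, the nursing cells of the tubules, showed 0 calls over all genes and 2 higher genes when adjusted over the list alone among 20 tested genes (median 0.05; camera adjusted p = 0.029; adjusted p = 0.754 with an estimated correlation). Those 2 were the cystatin genes Cst9, at 62.8 and 76.7 FPKM in the controls against 110 and 112 (log2 fold change 0.67, limma adjusted p over all genes 0.0601), and Cst12, at 56.3 and 74.5 against 107 and 109 (log2 fold change 0.73, limma adjusted p 0.0923). Aard and Rhox5 had log2 fold changes of 0.26 and 0.28. The list was not past the threshold without hemicastrated 1 (median 0.01, adjusted p = 0.252) or without control 2, where the median was -0.03 (adjusted p = 0.265), and it was lost with no filter, under quantile normalization and in TPM. Its median was 0.15 without control 1 and 0.08 without hemicastrated 2. The blood-testis barrier list had 0 calls among 10 tested genes by either adjustment (median -0.12, camera adjusted p = 0.575; median -0.003 without hemicastrated 1 and -0.01 without control 1), with the claudin gene Cldn3 at 24.3 and 20.2 against 16.9 and 15.1 FPKM.

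Leydig cells make testosterone. Of 17 tested genes of the Leydig and steroidogenesis list, 1 fell over all genes and over the list alone and 0 rose (median -0.13, camera adjusted p = 0.575; median 0.03 without hemicastrated 2 and -0.04 without control 1). The gene that fell was the prostaglandin D synthase Ptgds, from 598.1 ± 5.4 to 254.8 ± 52.8 FPKM (SD, n = 2 each; log2 fold change -1.24, limma adjusted p = 0.0108), which missed the threshold without control 1 (adjusted p = 0.127) or control 2 (adjusted p = 0.14) and with no filter (adjusted p = 0.0909). Crisp1, Adam7 and the smooth muscle genes fell too, but every lower gene is low in the same libraries, so this cannot tie Ptgds to them. The Leydig hormone gene Insl3 was at 1272 and 1232 FPKM in the controls against 1609 and 1484 (log2 fold change 0.30, limma adjusted p = 0.241), and Star, the cholesterol carrier into mitochondria, at 22.2 and 17.0 against 26.8 and 26.1 (log2 fold change 0.43, limma adjusted p = 0.335). The log2 fold change of Star was 0.61 without control 1 and 0.24 without control 2. Of the steroidogenic enzyme genes, none of which passed the threshold, Cyp11a1 was at 73.1 and 64.2 FPKM in the controls against 48.9 and 62.2, Cyp17a1 at 202 and 159 against 154 and 173, Hsd17b3 at 30.2 and 25.1 against 30.7 and 27.6, and Hsd3b1 at 41.6 and 43.9 against 48.6 and 37.2. Hsd3b6 had a log2 fold change of -0.29, and of -0.05 without control 1 and -0.52 without control 2, and Hsd11b1 at 1.65 and 1.54 against 1.12 and 0.275 FPKM (log2 fold change -0.66, -1.02 without hemicastrated 1 and -0.29 without hemicastrated 2). In the cholesterol synthesis list, 1 of 21 tested genes fell over all genes and 5 fell over the list alone, with a median of -0.17 (camera adjusted p = 0.00268; adjusted p = 0.754 with an estimated correlation). The called gene, Acat2, which joins acetyl groups at the start of the pathway, went from 5.46 ± 0.06 to 2.75 ± 0.11 FPKM (log2 fold change -0.79, limma adjusted p = 0.0473) and shares sequence with the neighbouring Acat3. It was lost without any 1 of the 4 libraries, with no filter, under each of the 3 other scalings and without the Defb, Wfdc and Spink genes, and Tm7sf2 (log2 fold change -0.76) was called without hemicastrated 1 (adjusted p = 0.0241). Msmo1 and Nsdhl had log2 fold changes of -0.44 and -0.60. The cholesterol list missed the threshold without hemicastrated 1 (adjusted p = 0.0695) or control 1 (median -0.11, adjusted p = 0.0837), had a median of -0.27 without control 2, and its lower values occurred in the libraries with lower Crisp1 and smooth muscle genes.

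Hormone response genes did not pass the threshold over all genes. The gonadotropin, androgen and activin list had 0 calls among 10 tested genes, and 1 higher and 1 lower over the list alone (median -0.04, camera adjusted p = 0.92). The luteinizing hormone receptor Lhcgr was at 5.34 and 2.34 FPKM in the controls against 1.30 and 2.13 (log2 fold change -0.78, SE 0.32). Its log2 fold change was -0.32 without control 1 and -1.24 without control 2. The prolactin receptor Prlr was at 4.72 and 5.05 FPKM against 2.51 and 2.86 (-0.68, SE 0.13), the inhibin subunit gene Inha at 31.8 and 29.6 against 34.1 and 37.2 (0.21, SE 0.10) and Inhbb at 3.15 and 2.51 against 3.16 and 2.16. The follicle-stimulating hormone receptor Fshr, at 0.951 and 0.730 FPKM in the controls against 0.306 and 0.824, and Amh, at 0.739 and 0.402 against 0.930 and 0.600, were under the filter and not tested. Inhba was under 0.05 FPKM in the 4 libraries, at 0.0279 and 0.0334 in the controls, 0.0384 in hemicastrated 1 and listed at 0 in hemicastrated 2.

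Genes of the DNA methylation machinery, which the title of the series names, showed 0 calls among 11 tested by either adjustment (median -0.05, camera adjusted p = 0.942). Dnmt1, the maintenance methyltransferase, had a log2 fold change of -0.06 (SE 0.13), its partner Uhrf1 of -0.15 (SE 0.15), the de novo enzyme Dnmt3a of 0.20 (SE 0.13) and its cofactor Dnmt3l of -0.05 (SE 0.22). The methyl-CpG binding gene Mbd1 was at 2.99 and 3.08 FPKM in the controls against 2.58 and 2.54, and Mbd4 at 2.13 and 2.77 against 2.58 and 1.21. Under the filter lay Dnmt3b, at 0.658 and 0.576 FPKM in the controls against 0.595 and 0.557, Tet1, at 0.0307 and 0.0405 against 0.0539 and 0.0498, Tet2, at 0.632 and 0.308 against 0.430 and 0.219, and Tet3, at 0.230 and 0.217 against 0.185 and 0.299. The piRNA pathway, which silences transposons in germ cells, had 0 calls among 19 genes by either adjustment (median 0.002, camera adjusted p = 0.577), with Piwil2 at 25.1 and 22.1 FPKM in the controls against 20.2 and 22.0, Asz1 at 8.07 and 10.7 against 10.4 and 11.3, Tdrd1 at 29.3 and 26.3 against 23.2 and 26.9, and Gtsf1 at 424 and 465 against 461 and 499.

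Of the remaining signalling and cell state lists, retinoic acid had 0 calls among 14 genes over all genes and 1 lower over the list alone (median -0.07, camera adjusted p = 0.575), with the retinal dehydrogenase Aldh1a1 at 307 and 280 against 206 and 220 FPKM (log2 fold change -0.46, limma adjusted p = 0.0925). The mitotic cell cycle list had 0 calls among 21 by either adjustment (median 0.07, camera adjusted p = 0.133), with Bub1 at 0.23 and Ccnb2 at 0.15 on the log2 scale. Its median was 0.12 without hemicastrated 2 and 0.005 without hemicastrated 1. Apoptosis had 0 among 12 (median -0.06, camera adjusted p = 0.577), with Casp8 at -0.35 on the log2 scale and at -0.18 without hemicastrated 1. The immediate early and stress list had 0 among 7 (median -0.04, camera adjusted p = 0.942), with Jun at 1.63 and 1.01 FPKM in the controls against 0.935 and 0.879 and Dusp1 at 2.81 and 2.48 against 1.64 and 2.66.

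Genes of the respiratory chain held 1 call in each direction. In the list of nuclear-encoded oxidative phosphorylation genes, 73 were tested, of which 1 rose and 1 fell by either adjustment, with 44 positive log2 fold changes and a median of 0.05 (camera adjusted p = 0.0104; adjusted p = 0.754 with an estimated correlation). The one that rose was Cox5b, and the one that fell was the ATP synthase subunit Atp5e, from 294.6 ± 8.2 to 138.4 ± 14.4 FPKM (SD, n = 2 each; log2 fold change -1.09, limma adjusted p = 0.00376), which missed the threshold without control 1 (adjusted p = 0.0527) or control 2 (adjusted p = 0.0675). Cox7b2 and Cox8a, further subunits of cytochrome c oxidase, had log2 fold changes of 0.38 and -0.45. The list's median was 0.10 without hemicastrated 1 and 0.01 without hemicastrated 2. Its adjusted p was 0.446 without hemicastrated 2, 0.175 without control 1 and 0.381 under quantile normalization. None of 7 mitochondrially encoded genes was called by either adjustment (median -0.06, mean -0.04, while the test pointed up, camera adjusted p = 0.993), with mt-Nd1 at 724 and 731 FPKM against 819 and 813. The median of the mitochondrially encoded list was -0.20 without hemicastrated 1 and 0.15 without hemicastrated 2. The cytosolic ribosomal protein list had 0 calls among 55 by either adjustment (median 0.03, camera adjusted p = 0.131), with Rpl9 at 1.03 and 1.39 FPKM against 2.79 and 3.91 and Rps3 at 159 and 163 against 117 and 132. It passed without hemicastrated 1 (adjusted p = 0.0375), with no filter (adjusted p = 0.0302), in TPM (adjusted p = 0.0161) and with the length and GC correction (adjusted p = 0.032).

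**Figure D3:**
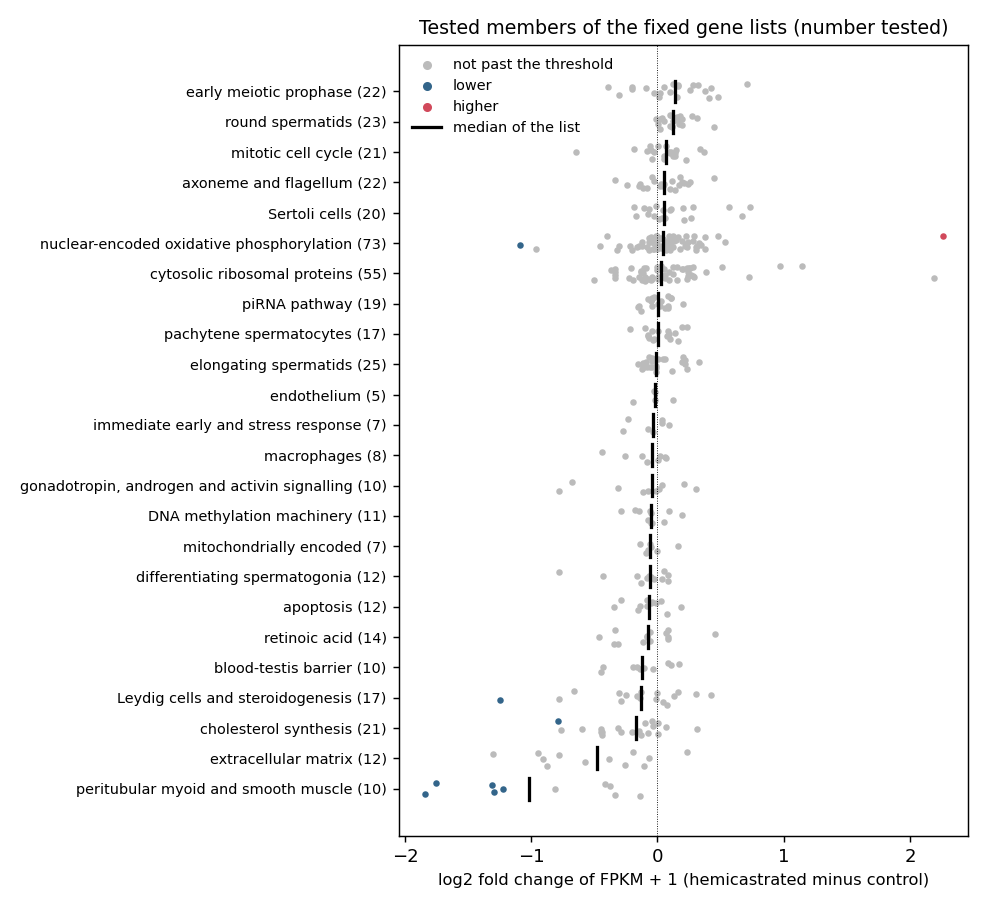
Log2 fold change (x axis, hemicastrated minus control, on the log2(FPKM + 1) scale) of the tested members of the 24 lists with at least 5 tested genes, 1 point per gene and a black bar at the list's median. The smooth muscle list has the lowest median, -1.02, and 5 of its 10 genes are called lower (blue), while 22 of 23 round spermatid genes lie above 0 with none called.

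With the preset correlation 7 of the 24 lists passed (smooth muscle, round spermatids, cholesterol synthesis, extracellular matrix, oxidative phosphorylation, early meiotic prophase and Sertoli cells), and 0 passed with an estimated correlation and 0 in fry. Of the 17 lists not past the threshold, 11 had a median that changed sign with 1 library left out. At an unadjusted p under 0.05 there were 0 lists with an estimated correlation and 1, smooth muscle, in fry. Among lists without a called gene, limma gave an unadjusted p under 0.05 for 7 early meiotic prophase genes, 5 round spermatid genes, 6 extracellular matrix genes, 8 cytosolic ribosomal protein genes, 3 Sertoli cell genes and 3 genes of the gonadotropin, androgen and activin list. It did so for 2 genes each of the blood-testis barrier and retinoic acid lists, for 1 gene each of differentiating spermatogonia, elongating spermatids and macrophages, and for 0 genes of the other lists without a call. Counted without a test, 157 genes were at least 2-fold apart with no overlap between the libraries of the groups, 19 higher and 138 lower. The other 2 ways to split the 4 libraries gave 41 and 18 such genes, though genes that differ between the groups tend to overlap in those splits. The libraries of the groups did not overlap for 41.2% of tested genes against 33.3% by chance.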

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

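The fit without secretory families and the length and GC correction were chosen after seeing the data. No called named gene or list was past the threshold in the other direction in any alternative; the median of the Sertoli list, 0.05, was -0.03 without control 2, where the list was not past it. Of 28 called named genes, 13 were called in every alternative in which they were tested and 15 were lost in at least 1, and 10 of 105 uncalled ones were called in at least 1. The higher genes (12) numbered 3 with no filter, 7 with a mean of at least 5 FPKM, 28 at a threshold of 0.1, and 0 to 26 with 1 library left out. The lower genes (135) numbered 63 with a mean of at least 5 FPKM, where 6873 genes were tested, and 78 to 156 with 1 library left out; without the secretory families they numbered 103. The lists past the threshold (7) numbered 4 under quantile normalization, 0 with an estimated correlation, 0 in fry, and 3 to 7 with 1 library left out. The genes 2-fold apart without overlap (157) numbered 271 with a pseudocount of 0.1, 64 with a mean of at least 5 FPKM and 376 in TPM, where 13691 genes passed the filter and the added 1 weighs less. For the other moves the cause was not tested. With a library left out, the lone library of its group is assumed to vary like the other group's pair. A block on the replicate number gave 30 higher and 167 lower genes, Bgn, Dcn and Col3a1 among the latter; the deviations of same-numbered libraries correlated at 0.0137 across genes, so the pairs share only a number. Depth is unknown, which limits what can be said of genes near 0.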

Other observations

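The families, neighbourhoods and single genes in the next 2 paragraphs were chosen after the values were seen. Of the 135 lower genes, 125 belonged to none of the fixed lists. Among tested genes, 9 of 17 beta-defensins fell (one-sided Fisher's exact test against all other tested genes, adjusted over 10 families, p = 8.21e-13), 7 of 12 genes of the whey acidic protein domain family (adjusted p = 1.09e-10), 5 of 7 Kazal-type inhibitors (adjusted p = 1.52e-08), 3 of 4 keratins, 3 of 9 S100 genes, 3 of 6 Ly6 genes and 4 of 15 serpins. By contrast, 1 of 27 Adam genes, 1 of 7 claudins and 0 of 5 cystatins with Cst symbols fell. Other members of these families did not pass the threshold: Defb19 was at 299 and 315 FPKM in the controls against 338 and 325, Defb36 at 33.8 and 37.7 against 37.9 and 35.3, and Spink2 at 431 and 437 against 465 and 477. Some uncalled members were lower. Defb10 was at 2.85 and 1.16 FPKM in the controls and listed at 0 in both hemicastrated libraries, and Defb21 and Wfdc6a had log2 fold changes of -0.47 and -0.38. Other genes that fell were Gpx3, the secreted glutathione peroxidase, at 214 and 242 against 5.51 and 2.80 FPKM, the aldose reductase relative Akr1b7 at 33.6 and 57.8 against 0.399 and 0.236, the class I light chain B2m at 134 and 176 against 39.9 and 36.1, Ly6e at 137 and 170 against 34.7 and 51.6, and the simple-epithelium keratin Krt18 at 2.63 and 2.51 against 0.124 and 0.258. Lactotransferrin Ltf was at 16.4 and 11.7 FPKM in the controls and listed at 0 in both hemicastrated libraries.

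Lower genes lay near each other more often than random tested genes. Of 134 lower genes with a position, 42 had another lower gene starting within 500 kb, against a median of 16 and a highest of 38 in 10000 random draws of as many tested genes. The draws took no account of families whose genes lie side by side, so this excess is not separate from the family counts above. The group with the most genes was on chromosome 2 from 164214454 to 164687706 (GRCm38) and held 8: Wfdc15b, Spint3, Wfdc8, Wfdc6b, Wfdc16, Wfdc9, Wfdc10 and Wfdc13. Spink5, Spink14, Gm10267 and Spinkl lay on chromosome 18 from 43963235 to 44175074, and Abca2, Clic3, Ptgds and Lcn12 on chromosome 2 from 25428703 to 25493911.

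Apart from the copy search and the length and GC correction, whose outcomes were set out before they were run, the tests below were chosen after the result was seen. For the 135 lower genes, tissue attached to the testis in both control samples is a candidate explanation, and the fixed smooth muscle list, of whose 12 genes 0 are in another list and 7 were at 1 FPKM or more in both hemicastrated libraries, held 5 lower genes among 10, more than the other tested genes (one-sided Fisher's exact test, p = 5.33e-08). Since the list also describes contractile cells of the testis itself and its fall was known when the test was chosen, this leaves muscle of an attached duct such as the distal epididymis or vas deferens open without singling it out. Of the 13 genes of the epididymis list, also fixed beforehand, 3 were tested, and Crisp1 and Adam7 fell while Rnase10 did not. The fall of Crisp1 and Adam7 goes with attached epididymal tissue, but both are among the genes to be explained. For the proximal epididymis, 0 of 8 listed genes reached 1 FPKM in both controls and stood above both hemicastrated libraries. In the controls, 3 are listed at 0 in both, Adam28 was at 0 and 0.0157 FPKM, Ovch2 at 0.0223 and 0, and Cst11 at 1.21 and 0. Rnase10 was at 2.02 and 1.28 FPKM against 1.59 and 1.70. Gpx5 was at 0.372 and 0.444 FPKM in the controls and listed at 0 in both hemicastrated libraries. Most of these values lie near 0, where a 0 can be a failed estimate, so this tissue stays open as well. Red blood cells are argued against, with a median log2 fold change of -0.21 for the 3 tested erythroid genes. That of Hbb-bs alone was -0.87 without hemicastrated 1. White blood cells are not covered by these 3 genes and stay open. A response of the remaining testis to hemicastration cannot be told apart from a difference in dissection, because 0 samples have labels that separate the operation from the dissection, and differences between outbred mice were not tested.

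For the 12 higher genes, 3 had a near-identical copy among the 12 searched, against 104 of 441 genes (23.6%) matched on expression to all 147 called genes, higher and lower. This argues against shared reads for the set as a whole but leaves Cox5b, Gm3543 and Itgb3bp uncertain. Dilution of testis RNA by other RNA in the controls would raise all testis genes alike. The median log2 fold change of all tested genes, which include those that other tissue would bring, was -0.0264. The medians of the early meiotic prophase, round spermatid, pachytene spermatocyte and elongating spermatid lists were 0.14, 0.12, 0.002 and -0.01. All lay under the smallest rise of the 12 (0.66), which argues against dilution as the cause of these rises. A response to hemicastration and a difference between outbred mice stay open, untested.

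For the round spermatid list, the call was lost with an estimated correlation (camera adjusted p = 0.754). However, 0 of the 24 lists passed that test, and smooth muscle, with 10 of 10 tested genes negative, was lost too. The loss therefore cannot decide whether correlation between the genes of the round spermatid list accounts for the small p. The median of all tested genes, -0.0264, lay under that of the list, 0.12, by more than their median absolute deviation (0.1155). It cannot decide on dilution of testis RNA, since the tested genes include those that other tissue would bring. Among other germ cell lists the median was 0.14 for early meiotic prophase, 0.05 for axoneme and flagellum and 0.002 for pachytene spermatocytes. It was -0.01 for elongating spermatids and -0.06 for differentiating spermatogonia. An equal rise of all germ cell genes was therefore not seen, which argues against an even dilution of them. Transcript length and GC content are argued against as the whole cause, since the median of the round spermatid list was 0.12 before and 0.11 after the correction. A shift in germ cell composition after hemicastration stays open, untested.

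Over all genes, 147 were past the threshold in the real split of the 4 libraries and 0 in either other split by limma, where 314 and 323 genes had an unadjusted p under 0.05 against 1191 in the real one. Only 1 of the 3 possible splits gave as many calls, and 3 splits are too few for a share under 0.05. Each side of the other splits mixes the groups, so the group difference widens the spread there and lowers the calls.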
